A study of Mus musculus with 2 samples.

How the data were processed

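The study profiled where the transcription factor p53 sits on chromatin in mouse kidney at E15.5 (embryonic day). Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used: proteins are fixed to DNA with formaldehyde, fragments held by an antibody are collected, and the recovered DNA is sequenced. Per the labels, 1 library was made with an antibody against p53 and 1 library from input DNA, which is chromatin without immunoprecipitation. Both came from wild-type kidney of the C57BL strain. One peak list, that of the p53 library, was analysed here. Peak-level data of the input library were not used here.

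The deposited list holds 5 fields per peak: chromosome, start, end, peak name and a score. Its track line names MACS, a peak caller that scans for windows with more mapped reads than a local background. Per the submitters' processing notes, MACS was the tool and mm9 the genome build. The aligner, the MACS version and settings, the treatment of duplicate reads and the use of the input library as the control are not given in the sources used here. Peaks were called on a single ChIP library, so no peak could be compared between replicates.

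The score of each peak is the authors' own value as deposited, 1 per peak. MACS writes -10 times the log10 of the peak's p-value in this position, and the values have that form, but the file does not state the scale. On that scale the lowest deposited score, 60.01, is a p-value of 1e-06. The score rises with the number of reads as well as with enrichment, and it stopped at 3100, so peaks at this value cannot be ranked among themselves. In the report, scores were used to describe, rank and filter peaks within the list. In the closing section they were also compared between neighbouring peaks, matched between X and autosomal peaks, and divided by 2 as a stand-in for signal, a use that assumes that score scales with signal. Starts and ends, counted from 0 at the start in the deposited list, are given 1-based below, in mm9. The file gives no read counts, so sequencing depth is unknown, and no interval on the signal of a single peak can be given. Intervals on numbers of peaks are exact (Clopper-Pearson for shares, Poisson for rates) at the 95% level and cover counting error only. They treat peaks as independent, which neighbouring peaks are not.

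No genome or annotation in mm9 was used here. Peaks were therefore not assigned to genes, and tests planned before the data were examined that needed one were not run: the share of peaks at transcription starts, the p53 consensus motif, and the nearness of peaks to the members of 14 gene lists. The planned test of each chromosome against its length was also not run, as lengths in mm9 were not used. The gene table at hand is of another assembly, GRCm38.p6. It was used only to count the protein-coding genes assigned to each chromosome, 21900 in all, and none of its coordinates was used. This count, and the use of the span from the first to the last peak of a chromosome in place of its length, were chosen after the data were examined.

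Peaks were counted per chromosome. Each chromosome's share of peaks was set against its share of the summed spans and of the genes with a two-sided exact binomial test, with Benjamini-Hochberg adjustment over 20 chromosomes. The test against genes was repeated over the 19 autosomes alone. Across chromosomes, Pearson's r and Spearman's rho were computed with permutation p-values from 100000 permutations. The 2 relations (with gene number and with span) were adjusted together.

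Grouping of peaks was tested by the share of peaks whose midpoint lay within 10 kb of another midpoint. It was set against 1000 random placements of as many peaks on each chromosome, over the span from its first to its last peak, in a two-sided permutation test. The smallest p-value these placements can give is 0.0020. The relation of score to width was described by Spearman's rho across peaks, which are not independent replicates, with a bootstrap interval over 1000 resamples of peaks. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

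The grouping test against uniform placement and the X value per gene were tried on simulated data first. The form of the grouping test in which each peak is moved by up to 500 kb was not simulated. With all 7893 peaks placed at random, 6 of 100 sets had p below 0.05 in the grouping test, each against 100 placements. With 10% of peaks put beside another, 20 of 20 sets did. In the form with peaks merged, 1 of 40 random sets did. When the X chromosome was given 30% of the autosomal peaks per gene, the mean recovered value was 30.0%. This checks the calculation only, because the same gene numbers set the counts and divided them.

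The peaks named were chosen by a rule fixed before the data were examined, for the case without coordinates of genes: the 10 highest-scoring peaks, the 5 widest and the highest-scoring peak of each chromosome. Because 15 peaks shared the highest score, all of them were named. Alternatives fixed before the data were examined were a score of at least 100, peaks within 1 kb of each other merged, other neighbour distances (1 and 100 kb), numbered chromosomes with X and Y only, and leaving out the widest 1% of peaks.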

Results

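The p53 ChIP-seq library of mouse kidney at E15.5 yielded 7893 peaks in the authors' call. p53 is a transcription factor that controls genes of cell cycle arrest, apoptosis and metabolism, and the embryonic kidney at this stage is still forming nephrons. The series sets 1 p53 library beside 1 input library, and the question it addresses is where in the genome p53 is bound in this tissue. With 1 library of each kind there was no replicate, so no value below carries a replicate error. The peaks were numbered from 1 to 7893 without a gap and covered 7.51 Mb in total. They lay on the 19 autosomes and the X chromosome.

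Most peaks were narrow and scored close to the lowest value in the list. The median width was 869 bp, with quartiles of 660 and 1142 bp and extremes of 193 and 6030 bp. The median score was 96.8, with quartiles of 73.4 and 143. Of all peaks, 4133 (52.4%) scored below 100, 3376 (42.8%) from 100 to below 300, 340 (4.31%) from 300 to below 1000 and 44 (0.557%) 1000 or more. Higher-scoring peaks were wider: the median width was 725 bp below a score of 100 and 1627 bp at a score of 1000 or more. Across peaks, Spearman's rho between score and width was 0.56 (95% bootstrap interval 0.55 to 0.58), and it was 0.38 among the 3760 peaks scoring at least 100.

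The highest-scoring peaks were 15 that shared a score of 3100, and they lay on 9 chromosomes. Chromosomes 2 and 19 carried 3 each. Those on chromosome 2 ran from 32306352 to 32308424, from 37558236 to 37560084 and from 49306531 to 49308958. Those on chromosome 19 ran from 7015204 to 7017324, from 10378902 to 10379892 and from 40662247 to 40664278. The narrowest of the 15, at 991 bp, was the one of these that began at 10378902. Chromosome 11 carried 2, from 69804159 to 69805705 and from 106076803 to 106078756. Chromosome 17 also carried 2, from 27759643 to 27761289 and from 39979847 to 39985876. Whether the peak that began at 39979847 lies in sequence present in many copies, where reads pile up in any library, was not tested. The others were on chromosome 1 (46909190 to 46911685), chromosome 6 (51418444 to 51421257), chromosome 9 (25059053 to 25061233), chromosome 14 (71165407 to 71167836) and chromosome 15 (79375925 to 79377983). Their median width was 2073 bp, compared with 869 bp over all peaks. The next highest score in the list was 2978, at a peak of 2417 bp on chromosome 7 (118225346 to 118227762).

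On the other chromosomes the highest-scoring peak stood lower. It reached 2328 on chromosome 12 (105989352 to 105990856) and 2202 on chromosome 4 (132894548 to 132895780). It reached 1564 on chromosome 18 (35113040 to 35115060), 1334 on chromosome 16 (38087682 to 38090601) and 1333 on chromosome 10 (46505329 to 46506052). It was 1308 on the X chromosome (160857166 to 160857944), 1135 on chromosome 8 (124356262 to 124356874) and 1080 on chromosome 13 (23830120 to 23832582). The lowest of these maxima were 839 on chromosome 5 (115939055 to 115940854) and 608 on chromosome 3 (80861958 to 80862875).

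The widest peaks were not all among the highest-scoring. The widest, 6030 bp on chromosome 17 (39979847 to 39985876), was at the highest score. The next was 5104 bp on chromosome 5 (143578680 to 143583783) with a score of 827. A peak of 4564 bp on chromosome 11 (62415798 to 62420361) scored 408, and one of 3955 bp on chromosome 13 (81022492 to 81026446) scored 608. The fifth, 3627 bp on chromosome 11 (96212644 to 96216270), scored 224.

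Peaks were spread unevenly over the chromosomes, and their number followed the number of genes. Chromosome 11 held the most, 696 peaks or 8.82% of all (95% interval 8.20 to 9.47), which was 5.87 peaks per Mb of the span between its first and last peak. Chromosome 19 held 5.02 and chromosome 17 held 4.41 peaks per Mb. Chromosome 1, with the longest span at 193 Mb, held 2.21 peaks per Mb, the lowest autosomal value. Across the 20 chromosomes, peak number was correlated with the number of protein-coding genes (Pearson's r = 0.86, Spearman's rho = 0.91, permutation p = 1e-05 for each, the smallest that 100000 permutations can give, adjusted p = 2e-05). Over the 19 autosomes alone r was 0.93 and rho 0.95. Without chromosomes 2 and 7, which lie farthest from the median gene number, r was 0.85. The relation with span was weaker in value (r = 0.39, permutation p = 0.087, adjusted p = 0.087, and rho = 0.48, permutation p = 0.034, adjusted p = 0.034). Over the 19 autosomes alone it was closer, with r = 0.57 (permutation p = 0.011) and rho = 0.67 (permutation p = 0.0021). Without chromosomes 1 and 19, farthest from the median span, r was 0.39 and rho 0.44, with permutation p-values of 0.11 and 0.066. The difference between the 2 relations was not tested.

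**Figure D1:**
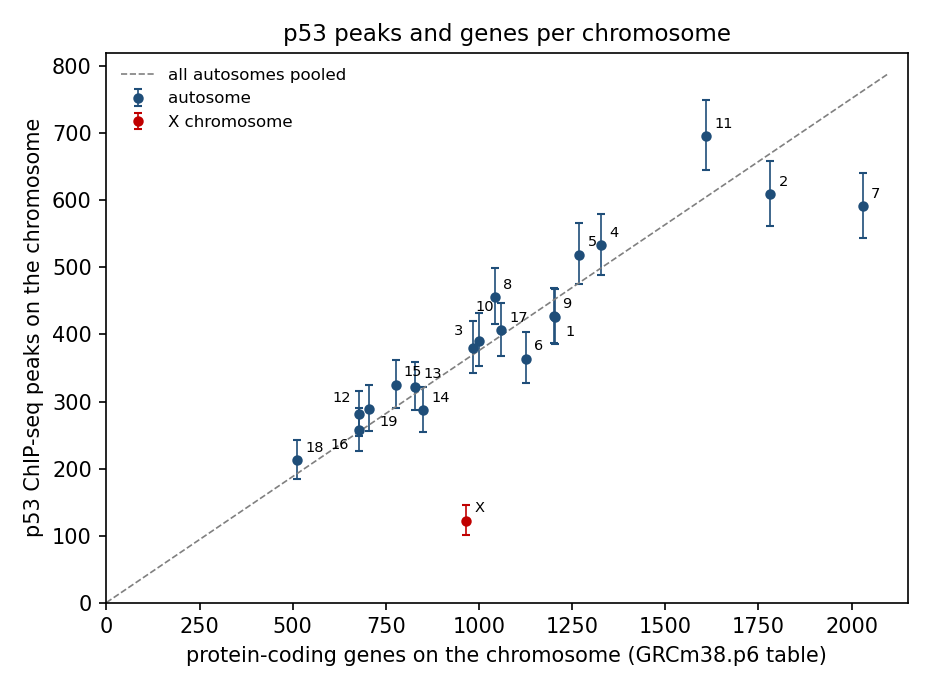
Number of p53 peaks (y axis) against the number of protein-coding genes (x axis) for each of the 20 chromosomes, numbered beside the points, with exact 95% Poisson intervals as bars. The dashed line is the pooled autosomal rate of 37.6 peaks per 100 genes, and the X chromosome lies below it at 12.6.

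The X chromosome stood apart from every autosome. It held 122 peaks, 1.55% of all (95% interval 1.29 to 1.84), where its share of the span was 6.24% and its share of the genes 4.47%. Per 100 protein-coding genes it held 12.6 peaks (95% interval 10.5 to 15.1), compared with 29.1 to 43.7 on the autosomes and 37.6 over all autosomes together. The X value was 33.6% of the pooled autosomal one (95% interval 27.9 to 40.2). The exact binomial test against gene share gave an adjusted p of 8.0e-46 over 20 chromosomes, a value that covers counting of peaks in this library only. Because the few X peaks raise the share of every autosome, the autosomes were also tested against gene share among themselves. Chromosomes 8 and 11 then held more peaks than their gene share, by factors of 1.16 and 1.15 (exact binomial test, adjusted p = 0.0076 and 0.0016 over 19 autosomes). Chromosomes 2, 6 and 7 held fewer, by factors of 0.909, 0.860 and 0.774 (exact binomial test, adjusted p = 0.049, 0.013 and 2.1e-10). With the X chromosome among the expected shares, chromosomes 5 and 15 also passed the test (factors of 1.12 and 1.15) and chromosome 2 did not. These autosomal factors depend on which genes are counted. Leaving out 2792 predicted, olfactory receptor and vomeronasal receptor genes moved the lowest autosome from 77.4 to 85.4% of the pooled autosomal rate. The tests of single autosomes were not repeated with that count. X peaks were also narrower, with a median of 611 bp where autosomal medians ranged from 839 to 945 bp. Their median score was 86.5, and autosomal medians ranged from 91.0 to 104.

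Peaks lay in groups more often than random placement gave, by a factor that depended on whether broad density was kept. Of 7893 peaks, 1562 (19.8%) had another peak within 10 kb, compared with a mean of 6.61% over 1000 random placements (central 95% from 5.89 to 7.37%), a factor of 2.99 (permutation p = 0.0020, the smallest the placements can give). Within 100 kb the shares were 72.4% and 48.7%. Among peaks scoring at least 100 the shares within 10 kb were 11.7% and 3.31%. Merging peaks separated by up to 1 kb left 7578 regions, of which 13.3% had another within 10 kb, compared with 5.34% in random sets merged alike. Where each peak was instead moved by up to 500 kb, which keeps the broad density of peaks along a chromosome, the mean share was 14.3% and the factor fell to 1.39. With peaks merged as well, they were 11.2% and 1.18 (permutation p = 0.0020 for each). Density that varies over shorter distances is not kept by such moves. The share with another peak within 10 kb, counted on unmerged peaks, did not rise steadily with score. It was 18.97% below a score of 100, 20.1% from 100 to below 300, 26.5% from 300 to below 1000 and 18.2% among the 44 peaks at 1000 or more. Against random sets of as many peaks, the class from 300 to below 1000 lay above chance (permutation p = 0.0046, adjusted p = 0.018 over the 4 classes), and the others did not pass the test (adjusted p from 0.13 to 0.97). Peaks in groups had a median score of 99.8 and a median width of 916 bp, and the others 96.1 and 858 bp. The median gap between consecutive peaks was 87.8 kb.

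**Figure D2:**
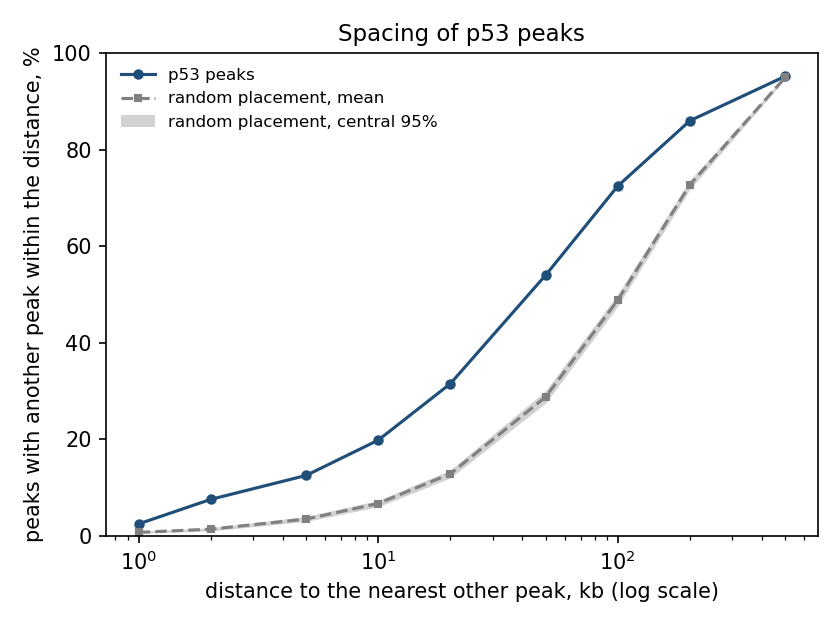
Share of p53 peaks with another peak within the given distance (y axis, %; x axis, kb, log scale), for the deposited peaks and for random placement (mean and central 95% of 100 placements per distance). The observed share lies above the random band at 10 kb (19.8%) and at 100 kb (72.4%) and meets it at 500 kb (95.2%).

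The densest stretch was on chromosome 13, and this and the regions that follow were chosen after their values were seen. From 23460636 to 23856043, 31 peaks lay within 395 kb, with scores from 62.1 to 1080 and a median of 169. Within it, 14 peaks fell between 23608558 and 23677555, the most in any 100 kb of the list. Random placement reached at most 8 peaks in any 100 kb over 1000 placements (permutation p = 0.0010, one-sided, the smallest they can give). These placements were uniform and used unmerged peaks, so they allowed neither for broad density nor for split regions. Several of the 31 peaks lay within 1 kb of the next, and the stretch was not counted again after merging. Other chromosomes with more than 8 were chromosome 6, with 11 peaks from 52108147 to 52196990, chromosome 11, with 10 from 69145403 to 69232965, chromosome 19, with 10 from 6983683 to 7071070, chromosome 10, with 9 from 80812759 to 80896230, and chromosome 17, with 9 from 35958326 to 36056857. The stretch on chromosome 19 holds the peak at 7015204 that reached the highest score. The longest stretches without a peak, leaving out chromosome ends, were on the X chromosome: 22.0 Mb from 108274502 to 130226493, 14.7 Mb from 50973974 to 65665748 and 13.6 Mb from 20539446 to 34137869. The longest on an autosome was 12.2 Mb on chromosome 15, from 13104624 to 25341694.

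**Figure D3:**
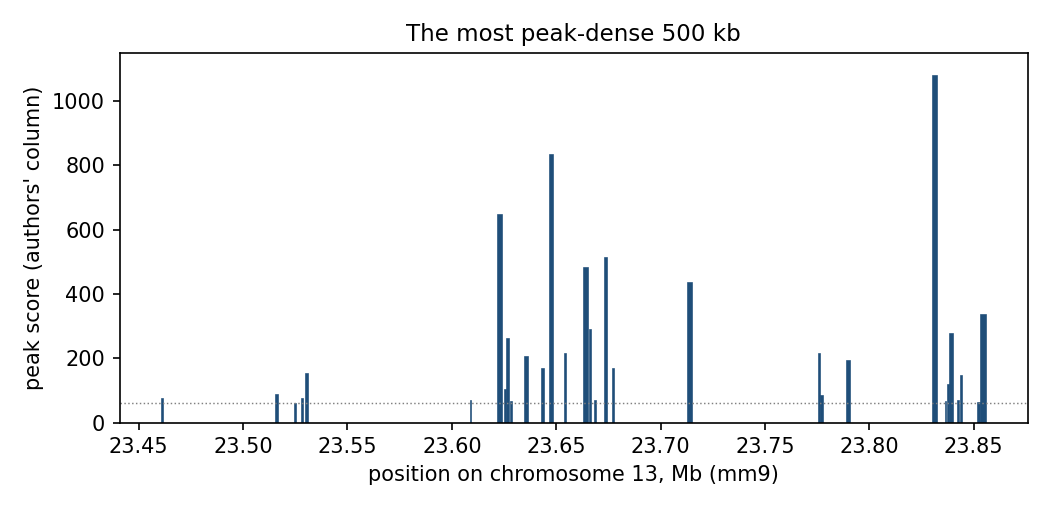
Map of the 31 peaks in the most peak-dense 500 kb (x axis, position on chromosome 13 in Mb, mm9), each drawn as a bar from its start to its end with its score as the height (y axis). The dotted line marks a score of 60, just under the lowest in the list, and the highest bar reaches 1080.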

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

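A score of at least 100 left 3760 of the 7893 peaks, raised the share on chromosome 11 to 9.52%, lowered the share on the X chromosome to 1.12% and lowered the correlation of score with width to 0.38. The lower peak number is the score filter itself. The lower correlation follows at least in part from the smaller set with its narrower range of scores, and for the chromosome shares the cause was not tested. Merging peaks within 1 kb and leaving out the widest 1% of peaks left the results to which each was applied, the grouping share aside, within their intervals or within 1.5 times. Keeping numbered chromosomes with X and Y only removed no peak, so it could change no result. The grouping share fell from 19.8 to 13.3% on merging, and it stayed above random placement with a permutation p of 0.0020 under each alternative run, those at 1 and 100 kb included. The X value stayed between 24.2 and 34.4% of the autosomal one per gene and was 23.6% of it per Mb of span, and the rank correlation of peak and gene number between 0.89 and 0.95, under alternatives chosen after the data were examined. Alternatives for the promoter, motif and gene list results were not run, as those results needed an annotation or genome in mm9. No paired analysis was possible because each group has 1 library. Depth is unknown, so whether more sequencing would add peaks near the lowest score, where most of the list lies, cannot be judged from it.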

Other observations

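Strong peaks lay in peak-rich parts of the genome. The 384 peaks scoring at least 300 had on average 9.31 other peaks from 10 to 500 kb away, above the central 95% of random sets of as many peaks, which ran from 7.23 to 8.59. The 4133 peaks scoring below 100 had 7.36, below their random range of 7.76 to 8.04. The hypothesis that strong sites lie apart in regions with fewer other peaks, stated before this value was computed, was not borne out. For the 44 peaks at 1000 or more the mean was 8.55, not distinguishable from random sets of as many peaks (permutation p = 0.55). Between neighbours within 10 kb, scores were not detectably related (864 pairs, rank correlation 0.03, permutation p = 0.32, random range -0.07 to 0.07).

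The tests on the X chromosome and the test of splitting and broad density together were chosen after the results they bear on had been seen. The low number of X peaks is not accounted for by gene number: X peaks per gene were 0.434 of the value on chromosome 7, the lowest autosome (95% interval 0.332 to 0.562). A candidate explanation is that X regions carry about 0.5 times the signal of autosomal ones, as a chromosome present or active in 1 copy per cell could. If scores scale with signal, which the file cannot show, halving them leaves autosomal peaks that scored at least 120.02. These numbered 13.1 per 100 genes (19 autosomes from 9.61 to 17.0), next to 12.6 on the X chromosome. Their halved scores had a median of 86.5 and quartiles of 70.2 and 117, next to 86.5, 69.5 and 114 for X peaks. The upper tail did not match as well: the 90th percentile was 175 when halved and 139.115 on the X chromosome. The X value lay just below the central 95% of random sets of as many halved scores (139.147 to 215, permutation p = 0.0498, adjusted p = 0.20 over 4 quantiles). At higher scores, each doubled for the autosomes, the X chromosome held 5.59 peaks per 100 genes next to 6.01 (at least 90.015), 3.002 next to 3.053 (at least 120.02), 0.518 next to 1.26 (at least 180.03) and 0.311 next to 0.653 (at least 240.04). The X value lay within the range of the 19 autosomes at all of these scores but 180.03. There 5 X peaks gave a 95% interval of 0.168 to 1.21, which overlapped the autosomal range of 0.823 to 2.11. That interval lay below the pooled autosomal value of 1.26, so at this score the X chromosome held fewer peaks than halving gives. The few X peaks at high scores leave open whether halving holds for the strongest peaks. Only a ratio of 0.5 was tried, and given the width of the autosomal range the match cannot single it out from other ratios. The labels give no sex for the embryos, so copy number in males and silencing of one X in females cannot be separated here, and differences in how well reads map to the X chromosome were not tested. The narrower X peaks are not accounted for by their lower scores: autosomal peaks matched on score had a median width of 808.5 bp (central 95% of sets from 752.5 to 881.5), next to 611 bp. Halving was set against peak numbers and scores only, so as tried here it leaves this difference in width unexplained.

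The grouping of peaks within 10 kb was tested against splitting of single enriched regions and against broad density. After merging within 1 kb, 13.3% of regions still had a neighbour, above the random range of 4.71 to 6.07%. This argues against splitting with gaps of up to 1 kb as the whole cause. Regions split with wider gaps were not merged, so splitting of that kind was not tested. Moving each peak by up to 500 kb, which keeps broad density, gave a mean of 14.3% (13.3 to 15.3%), below the observed 19.8%. Both together gave 11.2% (10.3 to 12.2%) next to 13.3%, so an excess by a factor of 1.18 remained. Such moves even out density that varies over distances shorter than the move. The excess can therefore include density at those scales as well as grouping within 10 kb. Closely spaced genes, or several bound sites at one gene, may account for the excess, and both stay untested without an annotation in mm9.

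The widest peak, 6030 bp on chromosome 17 from 39979847, was also among the 15 at the highest score. Whether it lies in sequence present in many copies, where reads pile up in any library, was not tested.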
